A study of Mus musculus with 18 samples.

How the data were processed

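RNA from 18 mouse tumors was measured with a NanoString nCounter panel for metabolic pathways, in which fluorescent barcodes bound to single RNA molecules are counted without amplification. The table read 782 probes, of which 768 were panel genes, 6 were positive controls and 8 were negative controls. Samples were assigned to 8 groups by their titles, which gave the kind of tumor, the arm and a replicate number. The labels do not say that the samples came from separate mice, so p-values here measure the spread between these samples.

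The values used are log2 values deposited by the authors. The only tool named for them, per the submitters' processing notes, is limma, and its role, its version, any background subtraction and any filter are not given in the sources used here. What was done to them was read from the values. In 12 columns, 2 to the power of each panel value less 1 stepped by 1 factor per sample, between 0.736 and 2.58, and 97.0% to 100% of the counts up to 500 recovered in this way were whole within 0.05. The factor set the mean log2 of 6 housekeeping genes (Cog7, Dnajc14, Oaz1, Sap130, Sdha and Ubb) to between 10.4804 and 10.4805 in those columns. The other 6 columns held whole numbers with a mean of those genes between 10.4835 and 10.5182, so it is not settled whether they hold counts or rounded scaled counts. They are replicate 1 of both control groups and replicate 2 of the DC1 and anti-semaphorin 4D groups of both kinds of tumor. Every combination sample lies in a scaled column. The pseudocount in the deposited values is 1, and control probes were left unscaled.

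Depth was taken as the sum of panel counts after the factor was removed. For every sample a limit was set at the mean plus 2 SD of its 8 negative control probes on the deposited scale, which gave log2 limits between 4.95 and 5.85. A gene at or below this limit in every sample of a group has only a bound there. Its change is given as "at least N-fold", which sets the mean of the brighter group against the mean, over the samples of the dim group, of the limit or the gene's own value, whichever was higher. No fold is given where this bound is under 1 or where both groups were dim. Folds are on the log2(count + 1) scale and understate changes of genes with few counts. The chi-square per degree of freedom between replicates was between 13.9 and 232, more than counting error alone would give, so no replicates within a group were copies of each other. It pools genes of all abundances, and the counting error of genes just above the limit was not measured.

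The deposited values were fitted without further scaling in limma 3.58.1 (R 4.3.3), with 1 mean per group over all 18 samples and no covariate. Moderated tests (lmFit and eBayes, trend and robust off) had 10 residual and 3.02 prior degrees of freedom. There were 22 comparisons, and p-values were adjusted by the Benjamini-Hochberg method over 768 genes within each, with a threshold of 0.05. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Symbols in the table were matched to RefSeq symbols of the GRCm38.p6 assembly for 767 genes, and 1 was kept as given.

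The groups, tests, gene lists, rule for named genes and first set of alternatives were set before the data were examined. Of 35 gene lists for pathways and cell types, 26 had at least 4 measured genes and were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists within a comparison. The same test with an estimated correlation called no list in any comparison, and its adjusted p is given beside each list. The rotation test fry, which asks only whether a list's genes move 1 way on balance, was run beside it. Counts "adjusted over the list alone" use only the p-values of the list's members. List medians are given relative to the median of all panel genes.

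Named genes were the 12 largest changes in each direction past the threshold for combination against control in each kind of tumor, and the 6 largest for every other comparison. Where fewer than 5 (or 3) passed in a direction, genes with the smallest p were added and are said not to pass. The 2 to 4 members with the smallest p were named from each list past its test. Cd8a, Cd3e, Gzmb, Ifng, Arg1, Nos2, Ido1, Cd274, Mki67, Ldha and Slc2a1 were always named. Sema4d, Plxnb1, Plxnb2 and Erbb2 were to be named too and were not analysed here. Housekeeping genes and control probes were left out of the naming. Some genes that met these rules are left out of the text. Cxcl9, Nkg7, Cd84, Nfkb2, Tnf, Mtor and Kynu in the treated tumor, Irf1, Tnf, Mtor and Pfkm in the untreated tumor, and Col6a1 and Cd84 between the 2 kinds of tumor in the combination arm are example genes, chosen from the fixed lists after their values were seen.

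The procedure was tested on simulated data, 20 sets of 768 genes with 200 changed. For combination against control in the treated tumor it recovered 17.1%, 56.6%, 90.6% and 99.0% of changes of 0.5, 1, 2 and 4 on the log2 scale, with 3.55% of calls false. In the untreated tumor the shares were 15.7%, 58.4%, 88.6% and 99.4%, with 4.10% false. For DC1 against control in the treated tumor, with 2 samples against 2, they were 11.3%, 49.9%, 86.7% and 99.1%, with 4.96% false. A shift of 1 in the T cell list was called in 100% of 50 sets, and 0.417% of the other lists were called. Genes were drawn independently of each other in these sets, with 1 spread per gene for all groups and changes of random direction. In the measured samples the spread differed between groups, and most calls for combination against control were of higher genes. These shares therefore do not give the share of false calls in the measured data. They also do not show how the test calls lists whose genes are correlated.

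Alternatives were median centring, quantile normalization, centring on the 20 housekeeping genes of the panel, a filter at the 25th percentile of mean value, eBayes with trend and robust, a fit of only the groups compared, the replicate number as a block, and each sample left out in turn. Those added after seeing the data were the kind of column as a block, only scaled columns, a filter on the negative-control limit, omission of the 2 samples with the fewest positive-control counts, and centring on the 14 housekeeping genes outside the deposited scaling.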

Results

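Tumors were grown from TUBO cells, a mouse mammary carcinoma line driven by the HER2/neu oncogene, in female BALB/c mice. Mice received dendritic cells designated HER2 DC1 into the tumor, an antibody that blocks semaphorin 4D, or both, for 3 weeks, and all tumors were taken at 1 time point. The 18 samples form 8 groups, from 2 kinds of tumor (treated and untreated) and 4 arms (untreated control, DC1, anti-semaphorin 4D and the combination). Each combination group had 3 samples and every other group had 2. Which tumor of an untreated control mouse counts as treated is not given in the sources used here.

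Panel counts before scaling ran from 203509 in replicate 2 of the untreated-tumor control and 238079 in replicate 1 of the untreated-tumor DC1 group to 989308 in replicate 1 of the treated-tumor anti-semaphorin 4D group. Between 518 and 609 of 768 genes exceeded the negative-control limit in a sample, 462 did so in every sample and 114 in none. Transferrin (Trf) was the most abundant transcript, with 9.70% to 20.4% of counts, in every sample except replicate 2 of the treated-tumor combination, where the MHC class II gene H2-Aa led with 4.82%. That sample also lay farthest out on the first principal component (58.7% of the variance), at 37.7 against 13.5 and 22.7 for its replicates. The lowest correlation between replicates, 0.928, was between it and replicate 1 of its group.

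The first comparison set the combination against control in treated tumors, where T cell transcripts were higher. Lat, the adaptor that relays signals from the T cell receptor, stood at 6.74 ± 0.74 (log2, SD, n = 3) against 1.00 ± 0.00 (n = 2) in control, at least 2.95-fold higher (adjusted p = 0.000301). The T cell surface proteins Cd6, Cd28 and Icos rose at least 5.09-fold, 4.63-fold and 5.67-fold, the kinase Zap70 at least 3.02-fold, and Cd4, the coreceptor of helper T cells, at least 5.12-fold (adjusted p from 0.000856 to 0.00194). Cd3e, part of the T cell receptor complex, rose at least 2.86-fold (adjusted p = 0.00723). Of 11 T cell markers, 9 rose and 2 did not pass, or 10 and 1 when adjusted over the list alone, and the list's median was 2.26 above that of the panel (adjusted p = 0.000488, and adjusted p = 0.745 with an estimated correlation). Of 18 genes of T cell receptor signaling and costimulation, 13 rose, or 15 adjusted over the list alone, with a median of 2.12 above the panel (adjusted p = 0.000467, and adjusted p = 0.745 with an estimated correlation). With dim members at their bound, the unadjusted medians were 1.56 in place of 2.80 and 1.58 in place of 2.66. All 3 combination samples lay above both controls for each of these genes. Every one of these gene calls held when any 1 sample was left out, with the highest adjusted p at 0.0496 for Cd3e without control replicate 1.

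Genes of antigen presentation and T cell inhibition were also higher in combination-treated tumors. The MHC class II gene H2-Eb1 rose 8.19-fold, from 11.13 ± 0.04 (n = 2) to 14.16 ± 0.98 (n = 3), and the MHC class I genes H2-M3, H2-T23 and H2-D1 rose 5.67-fold, 4.67-fold and 2.87-fold (adjusted p from 0.000856 to 0.00245). Of 9 antigen presentation genes, 8 rose, also when adjusted over the list alone, with a median of 1.36 above the panel (adjusted p = 0.00486, and adjusted p = 0.745 with an estimated correlation). The ligands of the inhibitory receptor PD-1 rose as well. Pdcd1lg2 (PD-L2) rose at least 21.4-fold to 9.61 ± 1.95 (n = 3; adjusted p = 0.000992), and Cd274 (PD-L1) rose 10.8-fold, from 6.07 ± 0.04 to 9.50 ± 1.14 (adjusted p = 0.00169). Pdcd1 (PD-1) rose 6.78-fold and Lag3, another inhibitory receptor, 3.79-fold (adjusted p = 0.00402 and 0.00665), the latter with adjusted p = 0.0526 without control replicate 1. Of 11 inhibitory checkpoint genes, 9 rose, also when adjusted over the list alone, with a median of 1.39 above the panel (adjusted p = 0.0203, and adjusted p = 0.745 with an estimated correlation), and 1.15 in place of 1.92 before adjustment with dim members at their bound.

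Interferon response and cytotoxic lymphocyte genes moved without passing as lists. Among 8 interferon response genes, 6 rose, including the chemokine Cxcl9 (14.3-fold, adjusted p = 0.00609), and the list had adjusted p = 0.0526. Among 14 cytotoxic lymphocyte genes, 10 rose, and this list also had adjusted p = 0.0526. The granule protein gene Nkg7 rose 8.37-fold (adjusted p = 0.0059) and the protease granzyme B (Gzmb) at least 2.77-fold (adjusted p = 0.0105, and 0.0886 without control replicate 2). Cd8a, Ifng and Ido1 were below the negative-control limit in both groups. Of 13 toll-like receptor and NF-kB genes, 8 rose (list adjusted p = 0.0816), among them Nfkb2 (4.18-fold, adjusted p = 0.00185) and the cytokine Tnf (3.18-fold, adjusted p = 0.00222, above the limit in 1 of 2 controls). Of 11 cytokines and chemokines, 7 rose (list adjusted p = 0.197).

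Lysosomal genes rose in the same tumors. Cathepsin D (Ctsd) rose 4.36-fold, from 10.51 ± 0.34 to 12.64 ± 0.72, and the lysosomal glucuronidase Gusb rose 3.91-fold (adjusted p = 0.00321 and 0.00249). Of 15 autophagy and lysosome genes, 11 rose, or 12 adjusted over the list alone, with a median of 0.779 above the panel (adjusted p = 0.0172, and adjusted p = 0.745 with an estimated correlation). Alox15, a lipoxygenase, rose at least 16.5-fold and Hk3, a hexokinase of blood cells, at least 13.5-fold (adjusted p = 0.000981 and 0.000946). Cd163, a scavenger receptor of macrophages, rose at least 6.23-fold with a wide spread (7.82 ± 3.05, above the limit in 2 of 3 samples, adjusted p = 0.0141), and Cd84 rose 11.2-fold (adjusted p = 0.00138). In all, 3 of 5 macrophage and monocyte genes rose, while the list had adjusted p = 0.487. Col6a1, a collagen VI chain, rose 15.5-fold and the extracellular superoxide dismutase Sod3, above the limit in 1 of 2 controls, 16.1-fold (adjusted p = 0.000301 and 0.00725). Replicate 2 exceeded the mean of the other combination samples by 3.77 (log2) for Cd163, 3.03 for Pdcd1lg2, 2.48 for Alox15 and 2.41 for Sod3. Without control replicate 1, adjusted p became 0.104 for Cd163 and 0.08 for Sod3. Without control replicate 2 it became 0.0586 for Cd163, and without combination replicate 2 it became 0.0527 for Cd163.

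Of 11 cell cycle genes, 4 fell, also when adjusted over the list alone, and the list's median was -1.35 relative to the panel (adjusted p = 7.39e-06, and adjusted p = 0.745 with an estimated correlation). Genes outside this list fell too. The ubiquitin-conjugating enzymes Ube2t and Ube2c fell 2.42-fold and 2.30-fold, the latter from 11.13 ± 0.02 to 9.93 ± 0.58 (adjusted p = 0.0045 and 0.0059). The nuclease Exo1, the Fanconi anemia gene Fanca and, from the list, the thymidine kinase Tk1 fell 2.22-fold, 2.23-fold and 2.11-fold, GMP synthetase (Gmps) 1.99-fold and, also from the list, the mitotic kinase Plk1 1.84-fold (adjusted p from 0.00762 to 0.041). The cyclins Ccna2 and Ccnb2 fell 1.82-fold and 1.76-fold (adjusted p = 0.0214 and 0.0475), while the log2 change of Mki67 was 0.31 (SE 0.47, adjusted p = 0.624). Folr1, a folate receptor, and Car12, a carbonic anhydrase, fell 2.80-fold and 2.55-fold (adjusted p = 0.014 and 0.00767). Ube2t and Ube2c kept their calls when any 1 sample was left out. Without control replicate 1, adjusted p became 0.0628 for Exo1, 0.215 for Fanca, 0.0573 for Tk1, 0.0785 for Gmps, 0.177 for Plk1, 0.101 for Ccna2 and 0.178 for Ccnb2. Without control replicate 2 it became 0.11 for Folr1, 0.0694 for Car12, 0.0804 for Fanca, 0.0871 for Tk1, 0.0568 for Gmps, 0.117 for Plk1, 0.097 for Ccna2 and 0.144 for Ccnb2. Without combination replicate 2 it became 0.104 for Fanca, 0.149 for Plk1, 0.0532 for Ccna2 and 0.165 for Ccnb2, and Plk1 had 0.0633 without combination replicate 3. Omission of untreated-tumor samples gave Plk1 up to 0.0529, and omission of samples of the other groups gave Ccnb2 up to 0.0606.

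Among metabolic lists, mitochondrial respiration passed its test. Subunits of respiratory complex I included the lower genes Ndufb2 (2.03-fold) and Ndufb8 (1.73-fold), as well as Ndufa12 (1.84-fold; adjusted p = 0.0279, 0.0177 and 0.0458). Of 19 mitochondrial respiration genes, 2 fell and 17 did not pass, and none passed when adjusted over the list alone. The list's median was 0.0182 on the deposited scale and -0.518 relative to the panel (adjusted p = 0.00485, and adjusted p = 0.745 with an estimated correlation), so its direction turned with the scaling. Without control replicate 2 the list had adjusted p = 0.0935, and Ndufb2, Ndufb8 and Ndufa12 had 0.223, 0.185 and 0.189. Without combination replicate 2 these genes had 0.103, 0.0645 and 0.163, and without combination replicate 3 Ndufb2 and Ndufa12 had 0.0565 and 0.0741. Ndufa12 also had 0.129 without control replicate 1 and up to 0.0596 without a sample of most other groups.

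None of the remaining metabolic lists passed. Of 18 glycolysis genes, 5 rose (list adjusted p = 0.487), while the log2 change was 0.50 (SE 0.54) for lactate dehydrogenase A (Ldha) and -0.50 (SE 0.35) for the glucose transporter Slc2a1 (adjusted p = 0.483 and 0.267). Of 17 MYC and mTOR genes, 8 rose (0.197), with the kinase Mtor up 2.89-fold (adjusted p = 0.00207). Of 8 fatty acid oxidation genes, 3 rose (0.969). Of 16 genes of arginine, tryptophan and kynurenine metabolism, 4 rose (0.487), with kynureninase (Kynu) up at least 5.09-fold (adjusted p = 0.00207), while arginase 1 (Arg1, log2 change 1.36, SE 0.58) and Nos2, above the limit in 1 of 3 combination samples and no control, did not pass (adjusted p = 0.0761 and 0.0722). Of 18 genes of the reactive oxygen response, 8 rose (0.948). In nucleotide synthesis, 4 of 23 rose and 2 fell (0.0526), in glutamine and amino acid synthesis 3 of 18 rose and 1 fell (0.487), and in the hypoxia response 1 of 8 rose and 1 fell (0.185). In the pentose phosphate pathway 3 of 7 rose (0.487), in amino acid transport 2 of 4 (0.44), in the TCA cycle 1 of 12 (0.139) and in fatty acid and cholesterol synthesis 1 of 6 (0.935), where the median was 0.0682 above the panel and the mean at -0.265. Among cell type lists, 1 of 5 B cell genes (0.937) and 2 of 7 neutrophil and mast cell genes (0.937) rose.

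Lists with fewer than 4 measured genes were not tested, and their members were read singly in treated tumors. The growth factor receptor Egfr rose 1.90-fold (adjusted p = 0.0187). Of the regulatory T cell genes, Il2ra rose 2.98-fold and Ctla4 at least 2.63-fold, above the limit in 2 of 3 samples (adjusted p = 0.0401 and 0.0074), while Foxp3 passed below the limit in both groups. The endothelial gene Flt1 rose at least 4.02-fold and the fibroblast gene Pdgfrb at least 3.54-fold (adjusted p = 0.00852 and 0.00928). The adipocyte gene Pparg rose at least 1.20-fold, above the limit in 1 of 3 samples (adjusted p = 0.002), and Cd36 did not pass (adjusted p = 0.115). The dendritic cell gene Flt3 and the muscle gene Eno3 did not pass (adjusted p = 0.121 and 0.168), and Pgam2 passed below the limit in both groups. Replicate 2 exceeded the mean of the other combination samples by 2.95 (log2) for Ctla4, 2.20 for Flt1 and 2.07 for Il2ra. The excess was 0.88 for Pdgfrb, 0.80 for Pparg and 0.73 for Egfr. No fit with a sample left out is reported for these genes. Their folds are on the deposited scale, where the median gene was 0.536 higher (log2). Lists for epithelial tumor cells and erythrocytes had 0 measured genes.

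**Figure D1:**
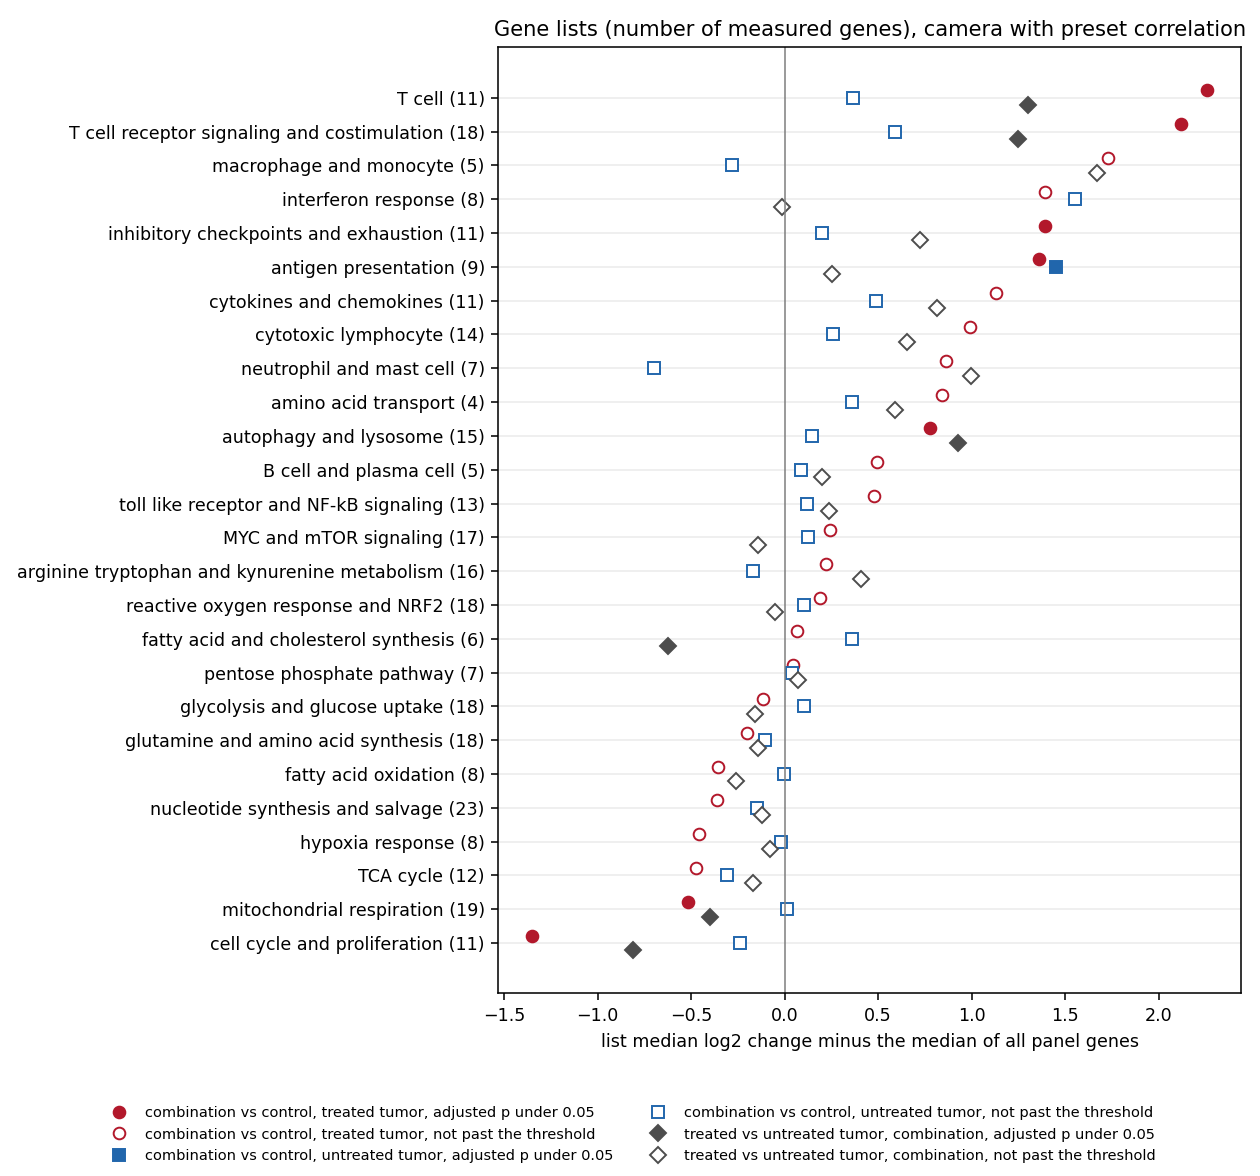
Median log2 change of each tested gene list relative to the panel median, for combination against control in treated and untreated tumors and for treated against untreated tumors of the combination arm, with marked points past an adjusted p of 0.05. The T cell list lies at 2.26 and the cell cycle list at -1.35 in treated tumors.

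In total, 298 of 768 genes differed between combination and control in treated tumors (limma, adjusted p under the threshold), 272 higher and 26 lower, and 68 of the higher genes came from below the negative-control limit in control. The median gene was 0.536 higher on the deposited scale. Median centring, which removed a shift of 0.708, gave 104 higher and 173 lower, and centring on 20 housekeeping genes, which removed 0.263, gave 193 and 72. In all 3 scalings 104 genes were higher and 26 lower. The count was 132 without control replicate 1, 137 without control replicate 2 and 195 without combination replicate 2. With the kind of column as a block it was 307. Among scaled columns alone, which leave 1 control sample, all 298 genes kept their sign. This is no support, because they were chosen from these same samples.

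In untreated tumors, the same comparison raised antigen presentation genes. The chemokine Cxcl9 rose 19.3-fold, from 6.21 ± 0.12 (log2, SD, n = 2) to 10.48 ± 1.47 (n = 3; adjusted p = 0.0105). H2-T23 rose 5.38-fold, from 10.14 ± 0.09 to 12.57 ± 0.79, H2-M3 4.75-fold, and the proteasome genes Psmb10 and Psme2, which act in peptide processing, 3.88-fold and 2.57-fold (adjusted p from 0.00216 to 0.0105). Of 9 antigen presentation genes, 7 rose, also when adjusted over the list alone, with a median of 1.45 above the panel (adjusted p = 0.00409, and adjusted p = 0.903 with an estimated correlation). Of 8 interferon response genes, 5 rose, among them Irf1 (3.23-fold, adjusted p = 0.0114), and the list had adjusted p = 0.19. Cd274 rose 7.40-fold, above the limit in 1 of 2 controls, and Pdcd1lg2 at least 1.56-fold (adjusted p = 0.00869 and 0.0324). Without control replicate 1 the list had adjusted p = 0.0888 and Pdcd1lg2 0.0549. Without control replicate 2 these genes had adjusted p between 0.0603 for H2-T23 and 0.233 for Pdcd1lg2. Without combination replicate 2 adjusted p became 0.0567 for Cxcl9, 0.0552 for Psmb10, 0.0585 for Irf1 and 0.121 for Pdcd1lg2, and without combination replicate 3 it became 0.0576 for Irf1 and 0.0999 for Pdcd1lg2.

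Other genes that rose in untreated tumors were the kynurenine pathway enzyme Haao, at least 1.58-fold (2.08 ± 0.34 to 6.25 ± 0.56, adjusted p = 0.000118), Hk3, at least 3.81-fold (adjusted p = 0.00819), and Sod3, at least 1.56-fold (adjusted p = 0.0324). Tnf rose at least 2.58-fold, the kinase Mtor 2.92-fold and phosphofructokinase (Pfkm) 2.49-fold (adjusted p from 0.00216 to 0.00819). Cdca5, a cohesin regulator, rose at least 3.16-fold (1.42 ± 0.59 to 7.26 ± 0.37, adjusted p = 0.0213). Lat passed the test (adjusted p = 0.0108) with 2 of 3 combination samples above the limit, and Ctla4 and Ptger4 passed (adjusted p = 0.0459 and 0.0196) with both groups below it, so no fold is given. The cytokine Il2 fell 2.07-fold, Klrb1a 1.99-fold and Tnfrsf4 1.91-fold (adjusted p from 0.0231 to 0.0498), with Il2 and Klrb1a above the limit in 1 of 3 combination samples. The circadian factor Clock, the mitochondrial NAD kinase Nadk2 and the transporter subunit Slc3a1 fell 1.80-fold, 1.80-fold and 1.60-fold (adjusted p from 0.0204 to 0.0394). Haao alone of these kept its call when any 1 sample was left out.

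The calls of the genes in the previous paragraph other than Haao ended without control replicate 2, with adjusted p from 0.0733 for Tnf and 0.0816 for Hk3 to 0.291 for Sod3 and 0.347 for Klrb1a. Without control replicate 1, adjusted p became 0.0642 for Cdca5, 0.051 for Lat, 0.233 for Ctla4, 0.0535 for Klrb1a, 0.116 for Tnfrsf4, 0.104 for Clock and 0.0935 for Slc3a1. Without combination replicate 2 the same genes and Sod3, Ptger4, Il2 and Nadk2 had adjusted p between 0.0575 for Lat and 0.146 for Klrb1a. Without combination replicate 3 all of these had adjusted p between 0.0518 for Lat and 0.115 for Ctla4. Without combination replicate 1, Klrb1a, Tnfrsf4 and Slc3a1 had 0.0687, 0.0733 and 0.0812. Omission of samples of other groups moved Ctla4 up to 0.0597, Klrb1a up to 0.0656, Tnfrsf4 up to 0.0558 and Slc3a1 up to 0.0539.

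T cell and proliferation genes gave fewer calls in untreated tumors. Of 11 T cell markers 2 rose (list adjusted p = 0.681), of 18 T cell receptor genes 3 rose and 1 fell (0.652), of 11 checkpoint genes 4 rose (0.652), of 14 cytotoxic genes 1 rose (0.933), and none of 11 cell cycle genes (0.652) or 5 macrophage genes (0.652) passed. Of 17 MYC and mTOR genes 6 rose (0.612), and of 19 respiration genes 3 rose (0.652). Cd3e, Gzmb and Nos2, below the limit in both controls and above it in 1, 3 and 2 of 3 combination samples, did not pass (adjusted p = 0.629, 0.201 and 0.195). Log2 changes were 0.18 (SE 0.58) for Arg1, 0.78 (SE 0.47) for Mki67, 0.69 (SE 0.54) for Ldha and -0.44 (SE 0.35) for Slc2a1, none of which passed. Cd8a, Ifng and Ido1 lay below the limit in both groups. In total 129 genes changed, 121 higher and 8 lower, 27 of the former from below the limit. The median gene was 0.449 higher. Median centring (shift 0.472) gave 26 higher and 19 lower and the 20 housekeeping genes (shift 0.261) 39 and 9, with 25 higher and 7 lower in all 3 scalings. Without control replicate 2, which leaves 1 control sample, all 129 genes kept their sign. This is no support, because they were chosen from these same samples. The count was 21 without combination replicate 2, 26 without combination replicate 3, and 4 with only the groups compared, which leaves fewer samples. With the kind of column as a block it was 198, and among scaled columns alone, which leave 1 control sample, 55.

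**Figure D2:**
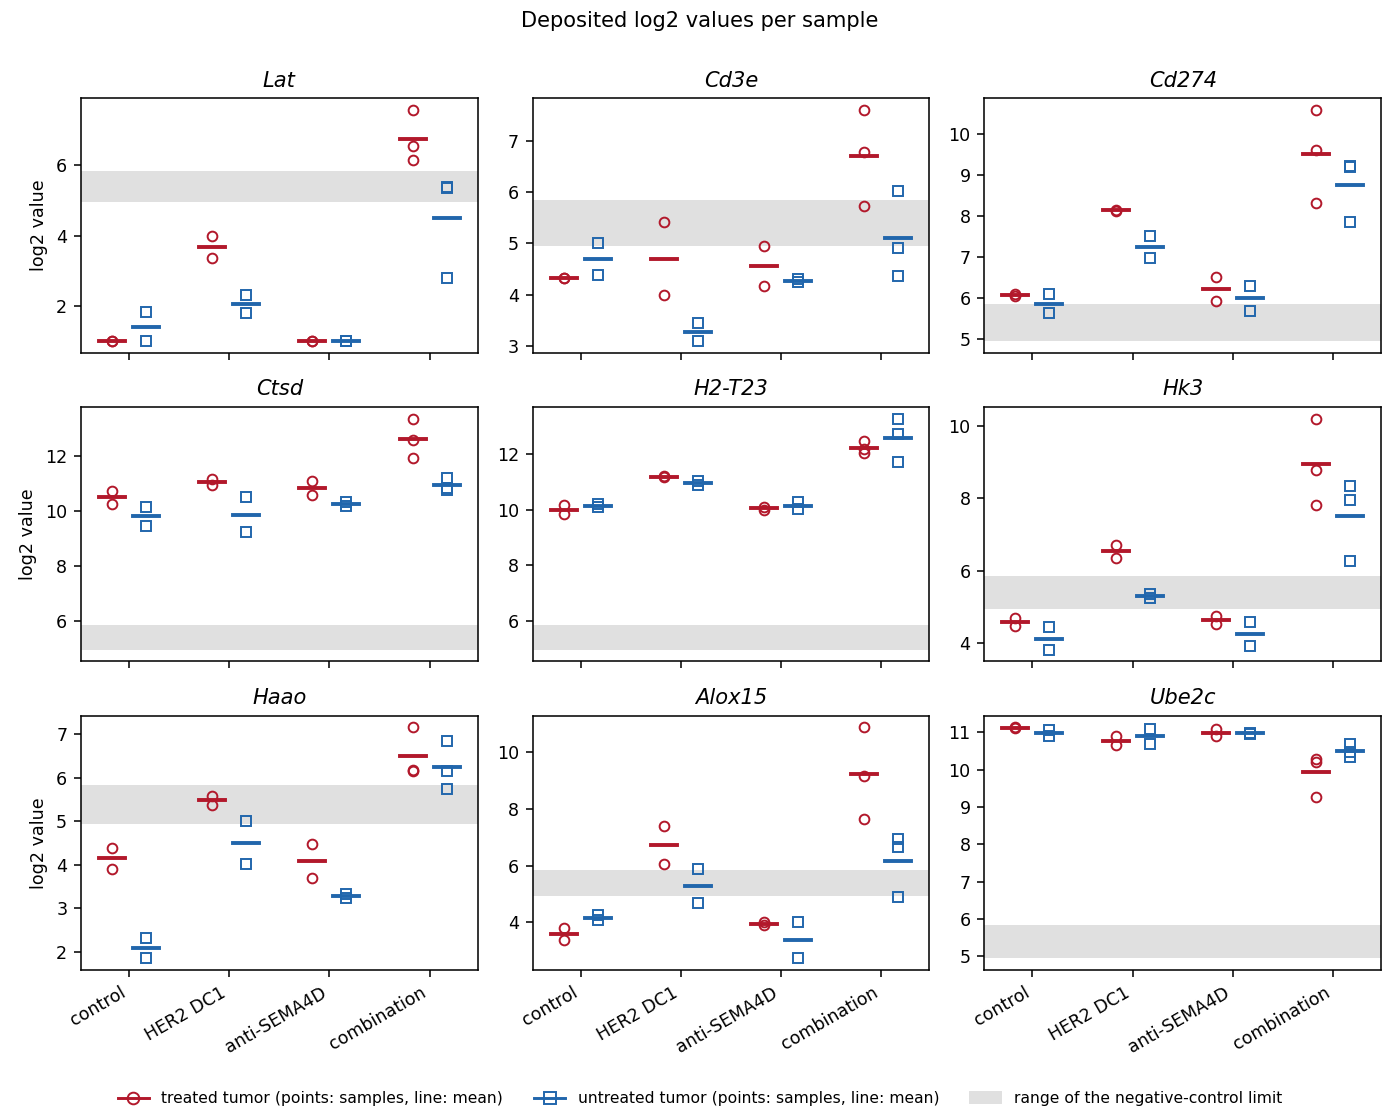
Deposited log2 values of 9 genes in each sample by group, with points for samples, lines for group means and a grey band for the range of the negative-control limit (4.95 to 5.85). Cd274 stands at 9.50 in treated and 8.75 in untreated combination tumors against 6.07 and 5.87 in control.

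The changes in the 2 kinds of tumor were compared. Across genes, which are not independent replicates, the fold changes of combination against control in treated and untreated tumors, which share no sample, correlated with r = 0.62. The changes with DC1 in treated tumors correlated with those of the combination in untreated tumors with r = 0.611, while those with DC1 in untreated tumors correlated with the combination in treated tumors with r = 0.21, again with no shared sample in either. The matching values for anti-semaphorin 4D in treated and in untreated tumors were r = -0.0263 and 0.0415. Of the 121 genes higher in untreated tumors, 98 were also called in treated tumors, against 42.9 for independent lists, and 107 lay above the panel median in treated tumors. Whether both kinds of tumor came from the same mice is not given in the sources used here, and genes are not independent, so these values are not tests. Of the 8 lower genes 3 were shared, against 0.271. Over the mean of both tumors, 370 genes changed, 339 higher and 31 lower (median gene 0.490 higher). This fit took all samples as independent, which understates the spread if 2 tumors of 1 mouse vary together. Deviations from group means correlated with r from -0.0675 to 0.52 between the 2 kinds of tumor for samples of the same arm and number. Median centring gave 122 and 184, centring on 20 housekeeping genes 241 and 82, and 122 higher and 31 lower genes held in all 3. Pdcd1lg2, Lat, Cxcl9, Hk3, Alox15 and Sod3 led with log2 changes of 4.63 (SE 0.63), 4.41 (SE 0.46), 4.06 (SE 0.62), 3.89 (SE 0.44), 3.80 (SE 0.58) and 3.74 (SE 0.68), fitted values that for dim controls are no bound. Nadk2, Ube2c, Exo1 and Car12 fell by 0.83, 0.84, 0.86 and 0.94. Glyat, a glycine acyltransferase, and Slc16a8, a lactate transporter, fell (adjusted p = 0.0149 and 0.0156; Glyat was below the limit in all combination samples and Slc16a8 in those of treated tumors), with 0.0662 and 0.0752 without treated-tumor control replicate 1 and 0.0794 and 0.0759 without untreated-tumor control replicate 2. Over both tumors, the lists for antigen presentation (adjusted p = 0.00444), T cell receptor signaling (0.0278) and T cells (0.0278) passed as higher. The cell cycle list passed as lower relative to the panel (adjusted p = 0.00261), although its members went both ways, with Tyms higher and Plk1 lower. Each of these lists had adjusted p = 0.955 with an estimated correlation.

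**Figure D3:**
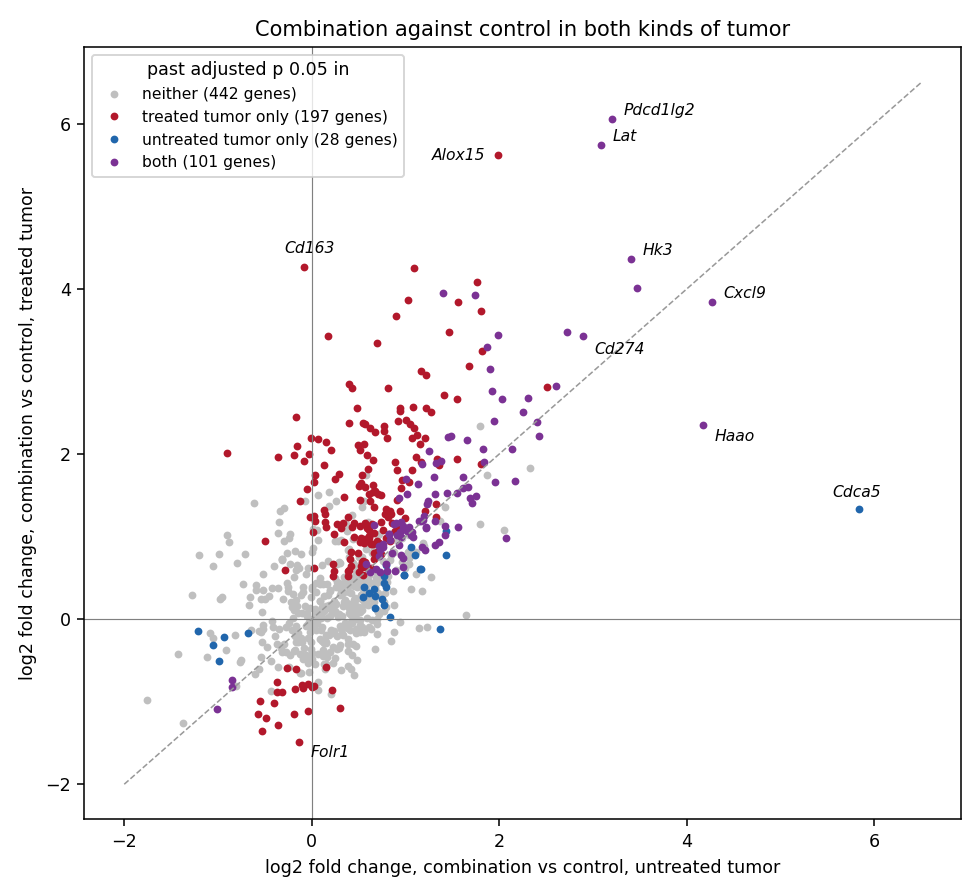
Log2 fold change of combination against control for 768 genes, in untreated tumors on the x axis and treated tumors on the y axis, with a dashed line of equality. Color marks genes past an adjusted p of 0.05 in both (101), treated only (197), untreated only (28) or neither (442).

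Whether the effect of the combination differed between treated and untreated tumors was tested directly. No single gene passed in limma, with 81 genes at an unadjusted p under 0.05. The smallest adjusted p, 0.392, belonged among others to Col6a1 (log2 difference 2.55, SE 0.64), while Tk1 had a difference of -1.38 (SE 0.42, adjusted p = 0.448). Without treated-tumor combination replicate 1, 19 genes passed. As lists, T cell markers (median difference 1.90, adjusted p = 1.36e-06) and T cell receptor genes (1.63, adjusted p = 1.01e-06) rose more in treated tumors, and cell cycle genes lay lower (-0.858, adjusted p = 8.84e-06), each with adjusted p = 0.635 with an estimated correlation. These list tests were not repeated with a sample left out. In untreated tumors 8 of the 11 T cell and 12 of the 18 T cell receptor genes were below the limit in the dimmer group. The size of the differences for these lists is therefore not known, and their adjusted p rests in part on values below the limit. For DC1 and anti-semaphorin 4D the same test called no gene, with 10 and 9 at an unadjusted p under 0.05. Nt5e, with a difference of 1.15 (SE 0.45), had adjusted p = 1 for DC1, and Foxp3 and Hnf4a, below the limit in all samples, had adjusted p = 0.999 for anti-semaphorin 4D. Without untreated-tumor DC1 replicate 2 the DC1 count was 2, and without treated-tumor anti-semaphorin 4D replicate 1 the anti-semaphorin 4D count was 1.

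Within the combination arm, treated tumors held more T cell transcripts than untreated tumors, and some macrophage genes were higher. Cd163 was at least 5.68-fold higher (7.82 ± 3.05 against 2.24 ± 0.36, SD, n = 3 each) and Cd209e, a C-type lectin, at least 1.09-fold (both with adjusted p = 0.0134, and above the limit in 2 and 1 of 3 treated tumors). Pdcd1lg2, Alox15 and Icos, above the limit in 2, 2 and 1 of 3 untreated tumors, rose 10.3-fold, 8.42-fold and 7.86-fold, Cd84 5.76-fold, and Col6a1 7.73-fold (adjusted p from 0.00285 to 0.0241). Nos3 passed (adjusted p = 0.0241) without a bound above 1. Cd28, Cd6, Lat and Cd3g, above the limit in 1, 1, 2 and 3 of 3 untreated tumors, rose 6.64-fold, 4.84-fold, 4.73-fold and 4.67-fold (adjusted p from 0.0232 to 0.034). Of 11 T cell markers 5 rose, or 10 adjusted over the list alone, with a median of 1.30 above the panel (adjusted p = 0.000364, and adjusted p = 0.792 with an estimated correlation). Of 18 T cell receptor genes 7 rose, or 15 over the list alone, with a median of 1.25 (adjusted p = 4.47e-05, and adjusted p = 0.792 with an estimated correlation). The lysosomal genes Ctsd, Gusb, Hexa and Ctsz rose 3.20-fold, 2.77-fold, 3.58-fold and 3.43-fold (adjusted p from 0.0232 to 0.0332), as did 6 of 15 autophagy and lysosome genes, or 10 over the list alone (median 0.926, adjusted p = 0.000645, and adjusted p = 0.792 with an estimated correlation). The macrophage list, with 3 of 5 genes higher, had adjusted p = 0.11.

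Of these genes only Col6a1 kept its call when any 1 sample was left out. Without untreated-tumor combination replicate 1, adjusted p was 0.0641 for Cd163 and Cd209e, 0.0657 for Cd84, 0.0808 for Icos, 0.0933 for Pdcd1lg2 and Alox15, 0.0916 for Nos3 and Ctsz, 0.0849 for Cd28, Cd3g and Gusb, 0.0918 for Cd6, 0.0816 for Lat and Ctsd and 0.0845 for Hexa. Without replicate 2 of that group it was 0.0599 for Pdcd1lg2, 0.0614 for Alox15, 0.086 for Nos3 and Cd6, 0.0941 for Cd3g, 0.0808 for Ctsd and Gusb, 0.118 for Hexa and 0.121 for Ctsz. Without treated-tumor combination replicate 2 it was 0.0584 for Icos, 0.111 for Pdcd1lg2 and Ctsd, 0.112 for Alox15, Nos3, Cd28, Cd3g and Cd6, 0.109 for Gusb, 0.131 for Hexa, 0.148 for Ctsz and 0.179 for Lat. Without replicate 3 of that group it was 0.0517 for Alox15 and Cd3g, 0.0626 for Hexa and 0.062 for Ctsz. Lat and Ctsz had values up to 0.0532 and 0.0512 without a control or anti-semaphorin 4D sample.

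Some genes were lower in the treated tumors of this arm. The thymidine kinase Tk1, the transcription factors Mybl2 and Mybl1, the cyclin Ccna2 and the condensin subunit Ncaph fell 1.97-fold, 1.88-fold, 1.81-fold, 1.79-fold and 1.72-fold (adjusted p from 0.024 to 0.0479), while Cdc20 and Tyms changed by -0.75 and -0.65 without passing. Of 11 cell cycle genes 2 fell, or 3 adjusted over the list alone (median -0.81 relative to the panel, adjusted p = 7.44e-06). None of 19 respiration genes (median -0.398, adjusted p = 0.00191) or 6 fatty acid and cholesterol synthesis genes (median -0.626, adjusted p = 0.0198) passed singly, and Acaca and Fasn changed by -0.39 and -0.46 on the log2 scale. With an estimated correlation, the respiration list had adjusted p = 0.854 and the other lists of this paragraph had adjusted p = 0.792. Ncaph had adjusted p = 0.0888 and 0.0732 without untreated-tumor replicates 1 and 2 and 0.109 without treated-tumor replicate 2. Tk1, Mybl2, Mybl1 and Ccna2 kept their calls in 6, 5, 4 and 4 of 18 fits, with the highest adjusted p at 0.136, 0.179, 0.215 and 0.179, all without treated-tumor replicate 2. The fatty acid list had adjusted p = 0.0642 without untreated-tumor replicate 2, 0.0606 without treated-tumor replicate 2 and 0.112 without treated-tumor replicate 3.

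In total 70 genes differed between treated and untreated tumors of the combination arm, 64 higher, 20 of them from below the limit, and 6 lower (median gene 0.257 higher). Median centring (shift 0.384) gave 35 and 48 and the 20 housekeeping genes (shift 0.189) 33 and 16, with 30 higher and 6 lower in all 3. The count was 5 without untreated-tumor combination replicate 1, 19 without replicate 2 of that group, 11 without treated-tumor combination replicate 2 and 158 without replicate 1 of that group. It was 38 without either treated-tumor control, 39 without either untreated-tumor and 40 without either treated-tumor anti-semaphorin 4D sample. Among scaled columns alone the count was 3. All combination samples are scaled columns, so the folds are the same there and only the spread lent by other groups differs.

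Either agent alone gave almost no calls, which with 2 samples per group does not show that it had no effect. DC1 against control called no gene in treated tumors (limma, 109 at an unadjusted p under 0.05) or untreated tumors (70). Smallest p in treated tumors belonged to the ectonucleotidase Nt5e (log2 change 1.46, SE 0.32), Runx2 (at least 1.98-fold) and Lat, below the limit in both groups, all with adjusted p = 0.288, and in untreated tumors to Haao, also below the limit in both groups (adjusted p = 0.0975). The untreated-tumor count was 8 without control replicate 1, 1 without DC1 replicate 2 and 1 without treated-tumor combination replicate 2, and the treated-tumor count was 1 without untreated-tumor combination replicate 1. Over both tumors 194 genes had an unadjusted p under 0.05, and only Haao passed (fitted log2 change 1.88, SE 0.32, adjusted p = 0.0411). It was above the limit in 1 of 2 treated-tumor DC1 samples and in no untreated-tumor DC1 or control sample. Its call ended with quantile normalization, either set of housekeeping genes, trend and robust, and the replicate number or the kind of column as a block. Vhl (1.10) and H2-M3 (1.30) had adjusted p = 0.0608. That count of 1 was 34 without untreated-tumor DC1 replicate 1, 11 without untreated-tumor control replicate 1, 9 without untreated-tumor combination replicate 1 or 2, 7 without treated-tumor combination replicate 1 or 2, 4 without treated-tumor DC1 replicate 1, and 0 in 9 other fits, where Haao reached adjusted p = 0.224 without untreated-tumor control replicate 2. The glycolysis list passed for DC1 in untreated tumors (adjusted p = 0.0431, and adjusted p = 0.969 with an estimated correlation).

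Anti-semaphorin 4D alone called no gene in treated tumors (limma, 11 at an unadjusted p under 0.05), in untreated tumors (25) or over both (26). The smallest p belonged to Gys2 and Hnf4a, below the limit in both groups, in treated tumors (adjusted p = 1) and to Slc16a6 (log2 change -0.94, SE 0.27) in untreated tumors (adjusted p = 0.947). Without untreated-tumor control replicate 1, the untreated-tumor count was 1. In treated tumors the cell cycle list (adjusted p = 0.00118) and the fatty acid and cholesterol synthesis list (0.0176) were lower without a gene past the threshold, each with adjusted p = 0.981 with an estimated correlation. Over both tumors the fatty acid (adjusted p = 0.0205) and cell cycle (0.0283) lists were lower and the NF-kB list (0.0443) higher, each with adjusted p = 0.98 with an estimated correlation.

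The combination was also set against each agent. Against anti-semaphorin 4D in treated tumors, 283 genes changed, 265 higher and 18 lower, led by Pdcd1lg2 (at least 18.3-fold higher), Alox15 (14.1-fold), Hk3 (11.5-fold), Icos (4.84-fold), Cd28 (3.95-fold) and Lat (2.52-fold), all bounds, with adjusted p from 0.000513 to 0.00154. Here 7 lists passed, with the T cell, T cell receptor and respiration lists at adjusted p = 0.000554 and adjusted p = 0.843 with an estimated correlation. With dim members at their bound the T cell and T cell receptor medians were 1.33 and 1.35. Folr1, Car12, Ndufb2, Ube2t, Ndufa12 and the nucleolar gene Npm1 fell by 1.35, 1.35, 1.25, 1.14, 1.11 and 1.07. Median centring gave 86 higher and 149 lower and the 20 housekeeping genes 184 and 56. The count was 106 and 166 without anti-semaphorin 4D replicates 1 and 2 and 183 without combination replicate 2. The higher genes named kept their calls in every such fit. Without anti-semaphorin 4D replicate 1, adjusted p became 0.162 for Folr1, 0.0577 for Car12, 0.136 for Ndufb2, 0.0684 for Ube2t, 0.156 for Ndufa12 and 0.211 for Npm1. Without replicate 2 of that group it became 0.053 for Folr1 and 0.0651 for Npm1, without combination replicate 2 it became 0.0658 for Ndufa12 and 0.126 for Npm1, and without combination replicate 3 it became 0.0622 for Npm1.

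In untreated tumors 96 genes changed between the combination and anti-semaphorin 4D, 93 higher and 3 lower. Haao rose at least 1.69-fold, Hk3 at least 4.09-fold, Cdca5 at least 3.40-fold and Cxcl9 10.5-fold (adjusted p from 0.00259 to 0.0292). Lat passed without a bound above 1 and Ctla4 with both groups below the limit (adjusted p = 0.0106 and 0.0337). Clock and Nadk2 fell by 0.80 and 0.76 (adjusted p = 0.0405 and 0.0291). Median centring gave 20 higher and 10 lower and the 20 housekeeping genes 55 and 4. The count was 0 without anti-semaphorin 4D replicate 1, 9 without replicate 2, 145, 3 and 21 without combination replicates 1, 2 and 3, 62 without either treated-tumor control and 150 without treated-tumor combination replicate 2. Without anti-semaphorin 4D replicate 1, adjusted p for these genes lay between 0.076 for Haao and 0.291 for Ctla4. Without replicate 2 it was between 0.0514 for Hk3 and 0.209 for Clock for all but Haao, and without combination replicate 2 between 0.052 for Lat and 0.144 for Clock. Without combination replicate 3, Cdca5, Cxcl9, Ctla4, Clock and Nadk2 had values from 0.0559 to 0.134, and Clock had values up to 0.0589 in 7 fits without a treated-tumor sample.

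Against DC1 in treated tumors, 14 genes changed, 13 higher and 1 lower. Col6a1 was 7.41-fold higher (log2 change 2.89, SE 0.45, adjusted p = 0.0172), Cd28 at least 3.68-fold and Lat at least 2.34-fold, and Pdcd1lg2, Icos, Cd6 and Pdcd1 had log2 changes of 3.86, 3.04, 2.56 and 2.48 with 1 of 2 DC1 samples above the limit (adjusted p = 0.0472 for these 6). Ube2t fell by 1.24 (adjusted p = 0.0472), and Cenpa changed by -0.94 without passing (adjusted p = 0.0554). In this comparison 9 lists passed, among them the cell cycle (8.96e-06) and respiration (7.48e-05) lists, lower, and the T cell receptor (2.12e-05) and T cell (7.48e-05) lists, higher, each with adjusted p = 0.728 with an estimated correlation. Median centring gave 5 higher and 2 lower genes and the 20 housekeeping genes 1 and 0. With the kind of column as a block no gene passed, Col6a1 included. The count was 0 without DC1 replicate 2, where Col6a1 had adjusted p = 0.103, 9 without DC1 replicate 1, 162 without combination replicate 1, and 2 without either treated-tumor control. It was 1 without combination replicate 2 or 3, either treated-tumor anti-semaphorin 4D sample or any untreated-tumor sample other than combination replicates 1 and 3, and the genes named other than Col6a1 then had adjusted p from 0.0539 to 0.163, as they had 0.0749 without either treated-tumor control. Without DC1 replicate 2 they had values from 0.24 to 0.329, without DC1 replicate 1 all but Cd6 had values from 0.0526 to 0.102, and Pdcd1lg2 and Ube2t had 0.0553 without untreated-tumor combination replicate 3.

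In untreated tumors no gene differed between the combination and DC1 (limma, 136 at an unadjusted p under 0.05). The smallest p belonged to the transporter Slc6a19, below the limit in both groups (adjusted p = 0.0642), to H2-T23 (log2 change 1.61, SE 0.33, adjusted p = 0.129) and to Tnf (adjusted p = 0.136). The antigen presentation list was higher and the hypoxia list lower (both adjusted p = 0.0167, and adjusted p = 0.952 with an estimated correlation). The count was 12 without DC1 replicate 2, 7 without combination replicate 1, 2 without treated-tumor combination replicate 1 or 2, and 1 without either treated-tumor DC1 sample.

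Whether the combination departed from the sum of both single agents on the log2 scale was tested for each kind of tumor. No gene passed in limma in treated tumors (69 at an unadjusted p under 0.05) or untreated tumors (53). The smallest p in treated tumors belonged to Col6a1 (2.43, SE 0.67), with adjusted p = 0.512, and in untreated tumors to Acaa2 (1.18, SE 0.34), with adjusted p = 0.611. In treated tumors 7 lists departed, with the T cell receptor (adjusted p = 5.87e-05) and T cell (0.00012) lists above the sum and the respiration (1.92e-05) and cell cycle (0.00855) lists below it, each with adjusted p = 0.824 with an estimated correlation. For the single agents 7 or 8 of the 11 T cell genes and 11 or 13 of the 18 T cell receptor genes were below the limit in the dimmer group. The size of these 2 departures is therefore not known, and their adjusted p rests in part on values below the limit. In untreated tumors 5 lists departed, among them the hypoxia (0.00593) and fatty acid synthesis (0.00747) lists, with adjusted p = 0.954 with an estimated correlation. The T cell list is not read here, since 8 of its 11 genes were below the limit in the dimmer group. In untreated tumors 2 genes departed without combination replicate 1, and 1 departed without control replicate 1 or DC1 replicate 2.

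Treated and untreated tumors of the other arms differed in no gene. Control mice gave 0 calls in limma (50 at an unadjusted p under 0.05; Haao, dim in both, had adjusted p = 0.392), DC1 mice 0 (100; Nt5e 1.02, SE 0.32, adjusted p = 0.371) and anti-semaphorin 4D mice 0 (14; Fbp1, dim in both, adjusted p = 0.999). In control mice the respiration list was higher in treated tumors (adjusted p = 0.0378, and adjusted p = 0.918 with an estimated correlation). The T cell list also passed (adjusted p = 0.0378, and adjusted p = 0.918 with an estimated correlation), but 8 of its 11 genes were below the limit in the dimmer group and its median was 0.00 with these at their bound, so no direction is read from it. The control count was 7 without untreated-tumor control replicate 1, and the DC1 count was 95 without untreated-tumor DC1 replicate 2 and 2 without treated-tumor combination replicate 2.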

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

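Results flagged for a closer look

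Responses to the combination differed between treated and untreated tumors in 8 gene lists, by a direct test of the difference. T cell markers (median difference 1.90, adjusted p = 1.36e-06) and genes of T cell receptor signaling (1.63, adjusted p = 1.01e-06), autophagy and lysosome (0.775, adjusted p = 0.02), cytotoxic lymphocytes (0.824, adjusted p = 0.0246) and inhibitory checkpoints (0.758, adjusted p = 0.0246) rose more in treated tumors. Genes of the cell cycle (-0.858, adjusted p = 8.84e-06), mitochondrial respiration (-0.534, adjusted p = 8.84e-06) and nucleotide synthesis (-0.198, adjusted p = 0.0459) lay lower there. With an estimated correlation the adjusted p was between 0.635 and 0.769. These list tests were not repeated with a sample left out. Replicate 2 of the treated-tumor combination exceeded the mean of its replicates in the T cell markers, by 0.685 (log2, Cd3d) to 1.94 (Sh2d1a). Part of the differences may therefore rest on that sample. In untreated tumors 8 of 11 T cell, 12 of 18 T cell receptor, 9 of 14 cytotoxic and 8 of 11 checkpoint genes were below the negative-control limit in the dimmer group. The size of the differences for these lists is therefore not known, and their adjusted p rests in part on values below the limit. The response to DC1 alone differed in 3 lists, T cell (0.843, adjusted p = 0.000986), T cell receptor (0.365, adjusted p = 0.0132) and hypoxia (-0.424, adjusted p = 0.00234), each with adjusted p = 0.876 with an estimated correlation. The medians of the T cell and T cell receptor lists were 0.00 in both kinds of tumor with dim members at their bound, so these 2 differences rest on values below the limit and are not read further.

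Counts stood above the control arm in control probes, which were not compared between groups. Negative control probes had a mean count of 18.667 in treated-tumor combination samples and 19 in treated-tumor anti-semaphorin 4D samples, against 13.938 in treated-tumor control. Positive control probes had 47950 counts in treated-tumor combination samples against 27880 in control. In untreated tumors they had 34567 in combination and 25725 in anti-semaphorin 4D samples against 12956 in control, a mean of 19363 and 6550, the latter in the sample with the fewest counts.

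Of the tests of the 3 patterns that follow, those of the deposited scaling and of few counts were chosen after the result was seen. The first pattern is the excess of higher over lower genes for combination against control in treated tumors. After centring on 14 other housekeeping genes, at least 60.4% of changed genes were higher with any 1 of the 5 samples compared left out. The excess therefore did not need the 6 housekeeping genes of the deposited scaling. This test cannot exclude the scaling as the cause, since it only puts 1 set of housekeeping genes in place of another. Background of dim probes was not the whole cause, since among genes above the limit in every sample the lowest such share was 79.9%. Median centring gave 104 higher and 173 lower genes, so the excess depended on the scaling. It removes any shift shared by most genes, whatever its cause, so it does not tell these causes apart.

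The second pattern is the distance of replicate 2 of the treated-tumor combination. It had 904880 panel counts against 844996 and 909415 in its replicates, so few counts were not the cause. A larger form of the change in the other combination tumors could not be told apart from another cause, with a lowest r of 0.122 across genes, which are not independent replicates. The genes with the largest excess in this sample were Cd163 (3.77), Nos2 (3.14) and Pdcd1lg2 (3.03).

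The third pattern is the T cell list, higher in treated than in untreated tumors of the combination arm. Without that sample the list median was still 0.882 above the panel, so the sample did not account for the whole of the median. The list test without it gave adjusted p = 0.00161 at the preset inter-gene correlation. This test cannot exclude the sample as the cause of the call, since it depends on that preset value. With an estimated correlation the list did not pass even with all samples (adjusted p = 0.792). Whether control mice held the same difference stays open, since 8 of 11 members were below the limit there and the median of -0.542 became 0.00 before adjustment with them at their bound.

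Samples were also regrouped within each kind of tumor. For the combination against control over both tumors, 1 of 100 splits, the real one, gave as many as 370 genes, and the highest other gave 310. This argues against chance only if all samples came from separate mice, which the labels do not say. If the 2 kinds of tumor are pairs from the same mice, there are 10 joint splits, too few to exclude chance. For DC1, 3 of 18 splits gave as many as the 1 gene found, with 66 in the highest other, and 18 splits are too few to exclude chance. For anti-semaphorin 4D, 18 of 18 splits gave at least the 0 genes found, which every split must, so nothing follows from it. For treated against untreated tumors of the combination arm, 1 of 10 splits gave 70 genes, and 10 splits are too few to exclude chance.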

How the results depend on the processing

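How the results depend on the processing

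Counts of changed genes are given for the alternatives that moved them most, and most smaller moves are left out. A smaller move was centring on the 14 other housekeeping genes for combination against control in treated tumors, which gave 158 higher and 82 lower genes. Chosen after the results were seen were the kind of column as a block, only scaled columns, the negative-limit filter, the omission of the 2 samples of fewest positive-control counts and the 14 other housekeeping genes. The cause was not tested unless stated. Only scaled columns leave 1 sample in every group outside the combination. For combination against control in untreated tumors (129 genes), the count was 45 with median centring, 51 with quantile normalization, 48 with centring on 20 housekeeping genes, 37 with the 14 other housekeeping genes, 4 with only the groups compared, which leaves fewer samples, 198 with the kind of column as a block, 55 with only scaled columns, and 1 without the 2 samples of fewest positive-control counts. In treated tumors (298) it was 155 with only the groups compared and 0 with only scaled columns, both with fewer samples. Over both tumors (370) it was 183 with only scaled columns.

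For combination against DC1 in treated tumors (14 genes), the count was 7 with median centring, 1 with the 20 and 1 with the 14 housekeeping genes, 37 with trend and robust, 0 with the kind of column as a block, 0 with only scaled columns, 35 with the negative-limit filter, which tests fewer genes, and 1 without the 2 samples of fewest positive-control counts. In untreated tumors (0) it was 12 with only scaled columns. Against anti-semaphorin 4D in treated tumors (283) it was 0 with only scaled columns. In untreated tumors (96) it was 30 with median centring, 29 with quantile normalization, 59 and 37 with the 20 and 14 housekeeping genes, and 1 with only scaled columns.

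For DC1 against control, the untreated-tumor count (0) was 1 with median centring. Over both tumors (1) it was 0 with quantile normalization, either set of housekeeping genes, trend and robust, the replicate number as a block, the kind of column as a block, only scaled columns, and without the 2 samples of fewest positive-control counts. It was 7 with the 25th percentile filter and 8 with the negative-limit filter, which test fewer genes. Between treated and untreated tumors, only scaled columns gave 3 genes in control, 4 in DC1 and 1 in anti-semaphorin 4D, each with 1 sample against 1, so that the spread came from the combination groups and these are not read as calls. They gave 3 in the combination arm (70), with the same samples and folds and a spread from fewer groups, and there omission of the 2 samples of fewest positive-control counts gave 107. The departure from the sum in untreated tumors was 1 with only scaled columns.

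For gene lists, combination against control in treated tumors gave 12 with median centring, 16 with fry and 0 with an estimated correlation. In untreated tumors it gave 2 with median centring, 2 with quantile normalization, 2 with the replicate number as a block, 7 with fry and 0 with an estimated correlation. Between tumors of the combination arm an estimated correlation gave 0. For combination against control over the mean of both tumors, Tyms changed from 0.60 to -0.0488 with quantile normalization. With each sample left out in turn, the count lay between 132 and 334 in treated tumors, 1 and 171 in untreated tumors, and 286 and 399 over both for combination against control, and between 5 and 158 for treated against untreated tumors of the combination arm. It lay between 0 and 162 for combination against DC1 in treated tumors, 106 and 323 against anti-semaphorin 4D in treated tumors, 0 and 150 against anti-semaphorin 4D in untreated tumors, 0 and 34 for DC1 over both tumors, 0 and 95 for treated against untreated tumors of the DC1 arm, and 0 and 19 for the difference in the effect of the combination. Count-model alternatives were not run, since it is not settled that every column holds counts. The sample with the fewest counts, 203509, was an untreated-tumor control. Without it 1 control sample was left there. All 129 genes kept their sign, which is no support, because they were chosen from these same samples.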

Other observations

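Other observations

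The probe for Cdca5, a cohesin regulator, rose in untreated combination tumors against control (1.42 ± 0.59 to 7.26 ± 0.37, SD, n = 2 and n = 3, adjusted p = 0.0213 in limma). Its call ended without control replicate 1 (adjusted p = 0.0642) or 2 (0.138) or combination replicate 2 (0.0848) or 3 (0.0597). The log2 change had an SE of 1.40. The probe also varied within other groups, above the negative-control limit in 1 of 2 treated-tumor control, treated-tumor anti-semaphorin 4D and untreated-tumor DC1 samples each. In treated tumors it did not pass (adjusted p = 0.468), and the difference between the 2 kinds of tumor did not pass either (adjusted p = 0.448).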
